A study of Mus musculus with 3 samples.

How the data were processed

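Gene expression was measured by single-cell 5' RNA sequencing (10x Genomics, 5' v2 chemistry) of live spleen cells from C57BL/6 mice, sorted on Calcein AM. There were 3 libraries: control, with 0 exposures to adeno-associated virus (AAV), single, with 1 exposure, and double, with 2. The design also mentions an injection for control mice, so what they received is not stated clearly. Each library pooled 3 mice, and spleens were taken 1 week after the last intravenous dose. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, and the count values are whole numbers. The submitters' processing notes name Cell Ranger 5.0.1, which the file header also gives, STAR 2.7.2a, whose role is not stated, and the mm10 genome. Each matrix held 32285 genes, of which 32158 identifiers were found in GENCODE vM21, the source of the coordinates (GRCm38). A further copy of each of 9 files was identical in 9 of 9 cases and was not used.

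The control, single and double libraries held 10770, 12403 and 9484 barcodes with 52115799, 51302403 and 46022538 UMIs. Barcodes with at least 500 UMIs, at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which removed 25, 45 and 23. Doublets were predicted within each library with the Scrublet caller of scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells. This removed 308, 589 and 226 cells (2.87%, 4.77% and 2.39%) and left 10437, 11769 and 9235. The cell numbers set the precision of a share: the smallest B-like subset, the germinal center-like cells of the control library, was 0.680% of cells with a 95% interval of 0.532 to 0.857%.

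Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes were taken over 20 bins of mean expression. Immunoglobulin and T cell receptor genes were left out of the clustering genes. Scaled values were clipped at 10, and 30 principal components, 15 neighbors, a shared neighbor graph and Leiden clustering at resolution 1 gave 31 clusters over the 3 libraries together. Clusters were named from 29 fixed marker lists and from their top 10 genes, ranked by the ratio of CPM with a prior of 10 CPM, so every class name is written with "-like". Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used, with random seed 1.

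Groups, comparisons, cell filters, marker lists, the 32 gene lists, the rule for named genes and 23 alternative settings were chosen before the data were examined. The naming thresholds were set after the clusters had been seen: a subset score of at least 0.2, a CD4 to CD8 margin of 1, a score of at least 1 for regulatory and follicular helper T cells, at most 30% of cells with both B and T transcripts, and markers detected in at least 10% of cells. The rule that left a cluster unnamed when its top 10 genes held more markers of another class was also set then. A further 7 alternatives were chosen after seeing the data. They left heat shock and immediate early genes out of the clustering, left out germinal center-like cells with T transcripts, cluster 5 or the germinal center-like cluster, or left out cells with transcripts of both lymphocyte classes.

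UMIs were summed per library and class and given as CPM, scaled to the total UMIs of that class in that library. Shares carry exact binomial (Clopper-Pearson) 95% intervals, CPM exact Poisson intervals, and ratios of CPM or of shares conditional exact binomial intervals. These intervals cover counting error only. Medians over cells and means per cell in the tests of cell mixing carry percentile intervals over 2000 bootstrap draws of cells. Because each group is 1 library there are no replicates, and no test between libraries, p-value or number of changed genes was computed. No difference between libraries has a replicate check. Ratios against 0 UMIs used a floor of 3 UMIs.

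For each gene list the median log2 ratio over members with at least 30 UMIs was set against 10000 random lists of genes matched in expression (each drawn from the 100 genes nearest in expression). Its percentile among them describes these libraries only. Genes are named in the report by rule: in each class with at least 300 cells per library (B-like and T-like), the 4 highest and 4 lowest ratios per comparison among genes with at least 50 UMIs and 20 CPM. Immunoglobulin, T cell receptor, mitochondrial, ribosomal, hemoglobin and sex-linked genes and unnamed gene models were left out of that choice. Members of a list are named by their absolute log2 ratio among members with at least 50 UMIs. Genes named on other grounds are said to be chosen after their values were seen. Percentages of cells with an Hspa1a UMI are given after thinning each cell to 1000 UMIs. Other counts and percentages of cells with a UMI, such as those in the tests of cell mixing, were made without thinning. A cell was called switched when its most abundant heavy chain constant gene, with at least 3 UMIs, was neither Ighm nor Ighd.

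The alternatives covered the cell filters, doublet removal, clustering resolution, clustering genes, class per cell in place of class per cluster, thinning, other scalings of the summed counts, the mean over cells, the UMI minimum of list members and the UMI minimum of an isotype call. The ratio and list steps were tested on simulated data made from the control library. All 50 genes planted at each of the folds 1.5, 2, 0.667 and 0.5 had intervals on the true side of 1. The interval held the true value for 95.4% of 9652 unchanged genes, and 2 of 100 unchanged lists lay outside percentiles 2.5 to 97.5. The simulated counts were independent Poisson draws at the UMI totals of whole libraries, the model on which the intervals are built. The simulation therefore checks the computation only. It does not cover the smaller sums of single classes or UMIs concentrated in few cells. Of the list and marker genes, 5 were not in the feature tables and were not used.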

Results

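The series concerns repeated gene delivery under targeted immunosuppression, and the libraries here address how the spleen differed after 1 and after 2 exposures to AAV. After filtering there were 10437 cells in the control library, 11769 in the single library and 9235 in the double library. In these cells median UMIs were 3788, 3329 and 3916, median genes 1539, 1397 and 1579, and median mitochondrial UMIs 1.69%, 1.64% and 1.69%. Each library pooled 3 mice, so values are given per library. The 2 comparisons against control share the control library and are not independent, while double over single does not use it.

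The main lymphocyte classes held similar shares in the 3 libraries. B-like cells were 58.4%, 58.6% and 58.9% of the control, single and double libraries, T-like cells 29.0%, 30.4% and 30.3%, NK-like cells 1.43%, 1.48% and 1.29%, and myeloid-like cells 2.34%, 2.41% and 2.36%. Germinal center-like cells, the antigen-driven B cells that mutate and switch their antibody genes, were 0.680% (95% interval 0.532 to 0.857%), 1.22% (1.03 to 1.44%) and 1.10% (0.901 to 1.34%). Plasma cell-like cells were 1.06%, 0.790% and 0.704%. Erythroid-like cells were 2.68%, 0.748% and 1.66%.

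Within the T-like cells, CD8-like cells were 13.4%, 15.2% and 14.5% of all cells, other CD4-like cells 8.63%, 8.64% and 8.38%, regulatory T-like cells 3.84%, 3.25% and 3.70%, and follicular helper-like cells 2.11%, 2.26% and 3.09%. Follicular B-like cells, the recirculating B cells, were 40.8%, 36.4% and 37.5%. Cluster 5, whose top genes were led by Hspa1a and Hspa1b, held most of them in the control library and clusters 0 and 1 in the others. It was 20.9%, 1.89% and 1.14% of the control, single and double libraries. Marginal zone-like cells (4.63%, 4.86% and 3.62%) and transitional-like cells (2.76%, 3.25% and 4.54%) gave directions that differed between clustering settings. Thresholds set after the clusters had been seen left 4.44%, 4.71% and 3.89% of cells unnamed, and 6.52%, 10.6% and 9.34% of cells in a B-like cluster without a subset name. They also left 0.958%, 0.994% and 0.650% in T-like and 1.25%, 1.09% and 1.13% in myeloid-like clusters without one.

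**Figure D1:**
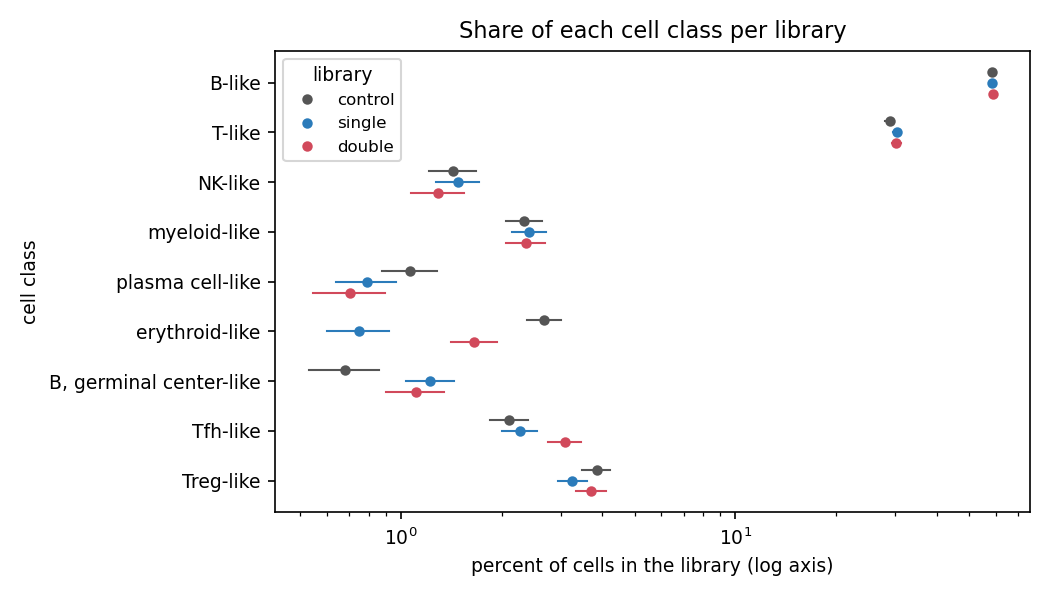
Share of the main classes in the control, single and double libraries, with exact binomial 95% intervals that cover counting error only.

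Single over control asked how the spleen differed 1 week after 1 exposure. The germinal center-like cluster held a larger share of cells, and B-like cells carried more germinal center transcripts. The cell cycle list was higher in all B-like cells together, but its size and its sign depended on which cells were kept. The medians of interferon and Toll-like receptor lists were close to control over all B-like and all T-like cells, while interferon lists were lower in myeloid-like cells. Heat shock 70 transcripts and the immediate early genes Fos and Jun, which cells make within minutes of stress, were lower in each of the 7 classes weighed.

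The germinal center-like share was 1.80-fold that of control (1.34 to 2.42), or 1.26-fold when each cell was classed from its own markers. The germinal center list had a median log2 ratio of 0.12 in B-like cells (percentile 100), with 14 of 19 measured members higher. Gcsam, a germinal center adaptor, was at 6.55 against 2.66 CPM (fold 2.46, 1.84 to 3.32). Mef2b, a transcription factor upstream of Bcl6, was at 1.95-fold (1.71 to 2.24), and Rgs13, a brake on chemokine signalling, at 15.8 against 8.91 CPM (1.78, 1.51 to 2.11). The cell cycle list had a median of 0.38 with 23 of 26 members higher, but 0.09 without B-like cells that had a Cd3e or Cd3d UMI. Without cluster 5 the germinal center and cell cycle medians were 0.07 and 0.05. Leaving out cluster 5 removed 2181 control and 222 single cells. This by itself raises the share of germinal center-like cells among the control B-like cells left, so the drop does not locate the difference. Without the germinal center-like cluster, which was formed and named on such genes, these medians were 0.02 and −0.11.

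Among B-like cells the highest genes by the fixed rule were the T cell chemokine Ccl5 (34.4 against 6.32 CPM, fold 5.43, 4.58 to 6.48) and the T cell membrane gene Ms4a4b (2.99, 2.56 to 3.51). The host transcript of miR-142, Mir142hg (2.05, 1.82 to 2.30), and the mitotic ubiquitin carrier Ube2c (2.02, 1.75 to 2.32) came next. Together, 6 T transcripts including Ccl5 and Ms4a4b had a log2 ratio of 1.41 (1.30 to 1.51), and 0.25 (0.11 to 0.38) without B-like cells that had a Cd3e or Cd3d UMI. The lowest were the heat shock genes Hspa1a (0.0620, 0.0568 to 0.0676), Hspa1b (0.102, 0.0969 to 0.108) and Hspb1 (0.162, 0.133 to 0.197), and the immediate early gene Fos (0.157, 0.143 to 0.172). Hspa1a and Hspa1b (chromosome 17, GRCm38 positions 34969190 to 34972156 and 34956436 to 34959238, ENSMUSG00000091971 and ENSMUSG00000090877) are near-identical copies, so the split of UMIs between them is uncertain. Their sum was 0.0865-fold that of control (0.0826 to 0.0906) in B-like cells and 0.107-fold (0.0974 to 0.118) in T-like cells. The 7 classes weighed were B-like, T-like, plasma cell-like, NK-like, myeloid-like, neutrophil-like and erythroid-like cells. Hspa1a was lower than control in 7 of 7, with the interval below 1 in 6, and Fos (chromosome 12, 85473890 to 85477273, ENSMUSG00000021250) was also lower in 7 of 7, with the interval below 1 in 6. The immediate early list had medians of −0.67 in B-like, −0.88 in T-like and −0.78 in myeloid-like cells, each at percentile 0.

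Not every heat shock gene followed. The list had a median of 0.07 (percentile 99.6) in B-like and −0.03 (percentile 33.9) in T-like cells, and −0.37 in myeloid-like cells. After thinning to 1000 UMIs, 24.6% of control and 2.18% of single B-like cells had an Hspa1a UMI (43.1% and 6% unthinned, 19 and 62 cells left out). In T-like cells the values were 9.28% and 0.568% (22.6% and 2.63% unthinned, 15 and 48 cells left out).

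In T-like cells the highest genes were the B cell receptor subunit Cd79a (35.1 against 18.2 CPM, fold 1.93, 1.67 to 2.24), Ly6k (1.60), the Fc receptor chain Fcer1g (1.57) and the class II gene H2-Eb1 (1.56). The lowest were Hspa1a (0.0712), Fos (0.0925, 0.0787 to 0.108), Hspa1b (0.127) and Jun, the partner of Fos in AP-1 (0.151, 0.139 to 0.165). The T cell activation list had a median of −0.35 (percentile 0). Its cytokines Ifng (3.26 against 9.43 CPM, fold 0.346, 0.246 to 0.479) and Tnf (12.8 against 27.6 CPM, 0.464, 0.390 to 0.551) were lower. The regulatory T list had a median of −0.21 (percentile 0), led by the repair factor Areg (2.43 against 8.17 CPM, 0.297, 0.201 to 0.431). The NF-kB target list was at −0.21 in T-like and −0.02 in B-like cells.

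Sensing and interferon lists lay near 0 in lymphocytes. The type I interferon list had medians of 0.07 in B-like (percentile 99.1) and 0.03 in T-like cells (95.4), and the Toll-like receptor and MyD88 list 0.01 and −0.03. In B-like cells Ifit3, an antiviral interferon target, was at 12.5 against 7.32 CPM (1.71, 1.42 to 2.07). Cluster 14, counted as follicular B-like, had Ifit3 and Irf7 among its top genes and was 1.18%, 1.44% and 1.39% of the control, single and double libraries. Cluster 30, counted as T-like, had Ifit1 and Ifit3 among its top genes and held 6, 15 and 4 cells. In myeloid-like cells the type I interferon list was at −0.23 and the interferon gamma list at −0.29, both at percentile 0. Lymphocyte lists were higher in the same cells, with the resting T list at 0.63 (percentile 100) and the B cell receptor list at 0.21 (99.6), and the cell cycle list was at −0.60. Monocyte-like cells were 38.9% (32.8 to 45.4%), 49.6% (43.7 to 55.6%) and 43.6% (36.9 to 50.4%) of myeloid-like cells in the control, single and double libraries, and cluster 15, which held C1qa and dendritic cell genes among its top genes, 53.3%, 45.1% and 47.7%. In all myeloid-like cells Ly6a was at 133 against 210 CPM (0.632, 0.533 to 0.748). The chemokine Cxcl9 was at 10.8 against 39.4 CPM (0.273, 0.153 to 0.464), with 40 of its 70 control UMIs in 1 cell.

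Plasma cell-like cells held 0.743-fold the control share (0.558 to 0.988) and erythroid-like cells 0.279-fold (0.217 to 0.355). The hemoglobin list was at −2.03 in B-like and −5.38 in T-like cells, both at percentile 0. How many cells carried the UMIs of this list was not examined in any comparison. CD8-like cells held 1.13-fold (1.06 to 1.22) and regulatory T-like cells 0.847-fold (0.734 to 0.977), the latter 1.02-fold when each cell was classed from its own markers.

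Double over control asked how the spleen differed after 2 exposures. The germinal center-like cluster was again larger than in the control library, and B-like cells held still more germinal center and cell cycle transcripts. The whole heat shock list was lower in B-like, T-like and myeloid-like cells, together with the immediate early list. Interferon and Toll-like receptor lists lay near 0 in these 3 classes.

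The germinal center-like share was 1.62-fold that of control (1.19 to 2.23), or 0.957-fold when each cell was classed from its own markers. The germinal center list had a median of 0.38 in B-like cells (percentile 100) with 16 of 19 members higher. Gcsam was at 10.1 against 2.66 CPM (3.79, 2.87 to 5.05), the nuclear GTPase Nuggc at 7.55 against 2.94 CPM (2.56, 1.94 to 3.42) and Mef2b at 2.23-fold (1.95 to 2.55). The cell cycle list had a median of 0.60 with 26 of 26 members higher. Without B-like cells that had a Cd3e or Cd3d UMI the medians were 0.49 and 0.41, without cluster 5 they were 0.25 and 0.31, and without the germinal center-like cluster 0.03 and −0.13. Here too cluster 5 held mostly control cells (2181, against 105 of the double library). Follicular helper-like cells held 1.46-fold the control share (1.22 to 1.75), and 1.05-fold when each cell was classed from its own markers. No such cluster was found at Leiden resolution 0.6 or after thinning.

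The highest B-like genes were Ccl5 (24.8 against 6.32 CPM, 3.93, 3.29 to 4.71), Ms4a4b (2.5, 2.12 to 2.95), Ube2c (2.5, 2.18 to 2.87) and Mir142hg (2.37, 2.11 to 2.66). Of the Ccl5 UMIs in double B-like cells (chromosome 11, 83525778 to 83530518, ENSMUSG00000035042), 371 of 566 (65.5%) lay in 1 cell, and the fold was 0.535 without B-like cells that had a Cd3e or Cd3d UMI. The lowest were Hspa1a (0.0385, 0.0343 to 0.0431), Hspb1 (0.0390, 0.0255 to 0.0572), Hspa1b (0.0670, 0.0624 to 0.0718) and Fos (0.160, 0.145 to 0.175). The sum of Hspa1a and Hspa1b was 0.0558-fold (0.0525 to 0.0592) in B-like and 0.0964-fold (0.0869 to 0.107) in T-like cells. Hspa1a was lower in 7 of 7 classes and Fos in 6 of 7, with neutrophil-like cells at 1.26-fold for Fos. The heat shock list was at −1.04 in B-like, −1.07 in T-like and −0.63 in myeloid-like cells, and the immediate early list at −0.70, −0.83 and −0.60, each at percentile 0. After thinning, 1.25% of double B-like and 0.646% of double T-like cells had an Hspa1a UMI (3.67% and 3.18% unthinned, 6 and 9 cells left out).

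The highest T-like genes were those of B cells, and 7 B transcripts summed had a log2 ratio of 0.53 (0.49 to 0.57), against 0.28 for single over control. The named genes were Cd79a (48.6 against 18.2 CPM, 2.67, 2.32 to 3.08; chromosome 7, 24897381 to 24902197, ENSMUSG00000003379), H2-Aa (2.15, 1.92 to 2.41), H2-Eb1 (2.00, 1.76 to 2.28) and Ly6d (1.89, 1.64 to 2.17). Without T-like cells that had a Cd79a or Cd79b UMI the folds of H2-Aa, H2-Eb1 and Ly6d were 0.891, 0.908 and 0.598. The lowest were Hspa1a (0.0750), Fos (0.104), Hspa1b (0.108) and Jun (0.172). The T cell activation list was at −0.13 (percentile 0.01), with Ifng at 6.79 against 9.43 CPM and the early activation antigen Cd69, also in the immediate early list, at 36.6 against 69.5 CPM (0.526, 0.474 to 0.585). Gzmb, a killing protease, was at 10.3 against 4.61 CPM (2.24, 1.68 to 3.01), detected in 41 and 36 cells, while the cytotoxic list was at −0.05 (percentile 2.79) with 10 members higher and 16 lower.

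In B-like cells the NF-kB target list was at −0.06 (percentile 0.1) and the B cell activation list at −0.10 (percentile 0.05). Cd83, a target in both, was at 232 against 354 CPM (0.656, 0.634 to 0.678). These values leave out cluster 10, whose markers were closest to B cells and whose top genes included Cd83, Nfkbid and Myc. It was left unnamed by the naming rule and held 3.09%, 2.81% and 2.95% of the control, single and double libraries. The type I interferon list was at −0.01 in B-like, 0.02 in T-like and 0.07 in myeloid-like cells, and the Toll-like receptor and MyD88 list at 0.03, 0.04 and −0.04. The complement list was at −0.54 in myeloid-like cells (percentile 0), with 6 of 12 members higher and 6 lower. The macrophage genes C1qa (52.4 against 141 CPM, 0.372, 0.284 to 0.483), C1qb (0.402, 0.317 to 0.508) and C1qc (0.413, 0.313 to 0.540) were lowest. They were among the top genes of cluster 15, which was 53.3% of control and 47.7% of double myeloid-like cells. A change in the make-up of the class was not separated from a change within its cells, and how many cells carried these UMIs was not examined. Plasma cell-like cells held 0.662-fold the control share (0.480 to 0.907) and erythroid-like cells 0.618-fold (0.504 to 0.755). The hemoglobin list was at −0.08 in B-like (percentile 21.8) and −4.46 in T-like cells (percentile 0), so it did not follow the erythroid-like share alike in both classes.

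Double over single asked how a further exposure differed from 1 alone. The germinal center-like share was alike, at 0.903-fold (0.693 to 1.17), while germinal center and cell cycle transcripts in B-like cells were higher. The heat shock chaperone Hsph1 was lower and the cold-inducible gene Rbm3 higher in each of the 7 classes weighed. In T-like cells activation transcripts and some effector transcripts were higher than in the single library, and in myeloid-like cells interferon transcripts were higher.

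The germinal center list had a median of 0.17 and the cell cycle list 0.20 in B-like cells (both percentile 100), or −0.04 and −0.01 without the germinal center-like cluster. Nuggc (1.76, 1.37 to 2.27), Gcsam (1.54, 1.26 to 1.90) and Mybl1 (1.54, 1.16 to 2.05) were highest. The highest B-like genes by rule were the DNA synthesis gene Rrm2 (27.6 against 15.6 CPM, 1.76, 1.55 to 2.01), the histone gene Hist1h2ap (1.74, 1.52 to 2.01), Rbm3 (634 against 428 CPM, 1.48, 1.45 to 1.52) and the replication factor Pclaf (1.48, 1.36 to 1.60). The lowest were the chaperone Hsph1 (57.5 against 210 CPM, 0.273, 0.257 to 0.290), the collagen hydroxylase P4ha1 (0.324, 0.282 to 0.372), and the co-chaperones Ahsa2 (0.339, 0.315 to 0.365) and Stip1 (0.404, 0.384 to 0.424).

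Hsph1 (chromosome 5, 149614287 to 149636376, ENSMUSG00000029657) was lower than in the single library in 7 of 7 classes with the interval below 1 in 6. Rbm3 (chromosome X, 8138975 to 8145880, ENSMUSG00000031167) was higher in 7 of 7 with the interval above 1 in 6. Against control, the single library had Rbm3 lower in 7 of 7 (interval below 1 in 6) and Hsph1 higher in 6 of 7 (above 1 in 4). Cirbp, another cold-inducible gene chosen after values were seen, was higher in 5 of 7 in the double than in the single library, with the interval above 1 in 2 and below 1 in 1 (erythroid-like cells, 0.506, 0.315 to 0.812). The heat shock list was at −0.83 in B-like, −0.49 in T-like and −0.25 in myeloid-like cells. The sum of Hspa1a and Hspa1b was 0.645-fold (0.599 to 0.694) in B-like and 0.899-fold (0.786 to 1.03) in T-like cells.

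**Figure D2:**
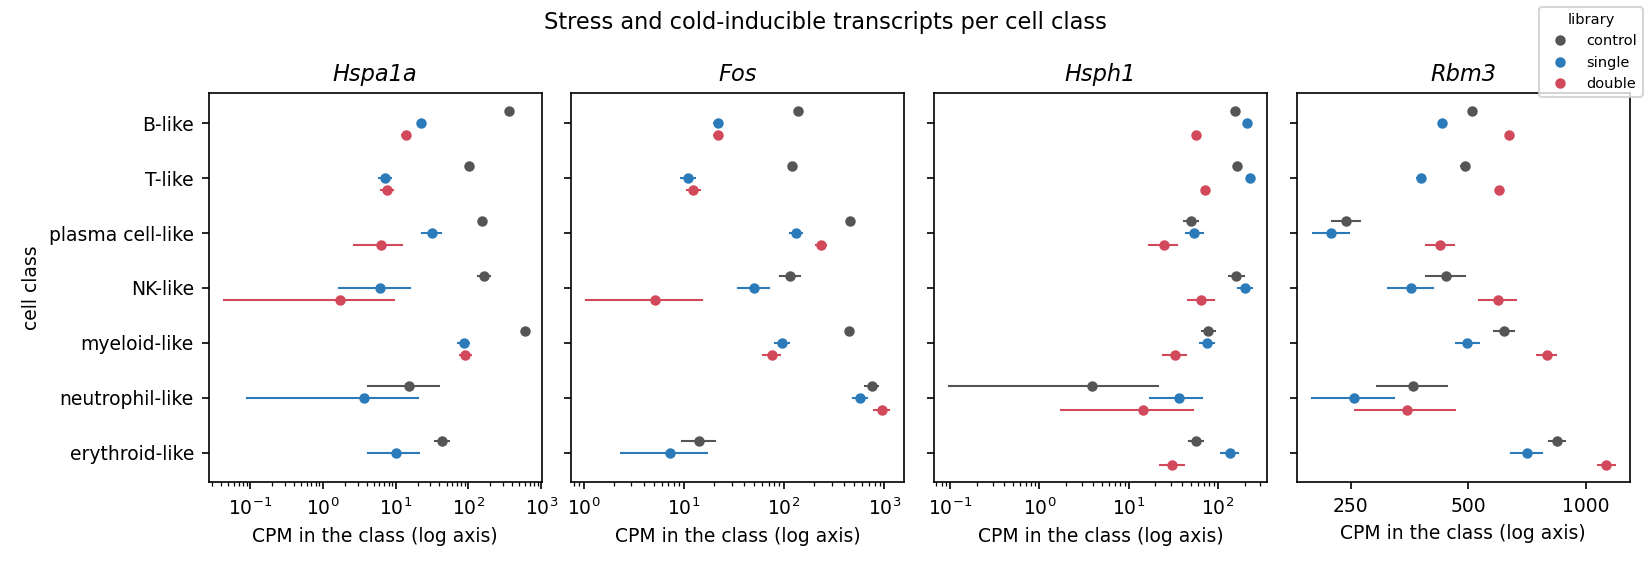
CPM of stress genes per class in each library, with exact Poisson 95% intervals. Classes with 0 UMIs are not drawn (Hspa1a in neutrophil-like and erythroid-like cells and Fos in erythroid-like cells of the double library).

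The highest T-like genes were the granzyme Gzma (20.9 against 8.44 CPM, 2.47, 2.01 to 3.05, from 21 and 31 cells, with 22.7 CPM in the control library), the motility gene S100a4 (1.79, 1.62 to 1.97), Rbm3 (1.59, 1.54 to 1.64) and the redox gene Glrx (1.57, 1.40 to 1.77). The lowest were Hsph1 (0.310, 0.289 to 0.332), Ahsa2 (0.381), P4ha1 (0.428) and the heat shock gene Hspa4l (0.440). The T cell activation list was at 0.14 (percentile 100), with Ifng at 6.79 against 3.26 CPM (2.08, 1.47 to 2.98) and Icos, a helper costimulator, at 1.30-fold (1.18 to 1.43). The immediate early list, which shares members with it, was at 0.17 in T-like cells (percentile 100, 18 of 23 members higher), against 0.06 in myeloid-like and 0.02 in B-like cells. The regulatory T list was at 0.20 (percentile 100), with Areg at 2.26-fold (1.52 to 3.42) and Nrp1 at 1.45-fold (1.22 to 1.73). Among members of the cytotoxic list, Klrg1 was at 7.06 against 2.49 CPM (2.83, 1.94 to 4.21), with 9.36 CPM in the control library, and Gzmb at 10.3 against 4.86 CPM (2.12, 1.60 to 2.84), while the list median was 0.02. Follicular helper-like cells held 1.37-fold the single share (1.15 to 1.62), or 0.858-fold when each cell was classed from its own markers.

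In myeloid-like cells the type I interferon and interferon gamma lists were both at 0.24 (percentiles 99.96 and 99.93). In the same cells the resting T list was at −0.49 (percentile 0) and the cell cycle list at 0.79 (percentile 100). Ly6a was at 269 against 133 CPM (2.03, 1.71 to 2.40) and the viral restriction factor Bst2 at 882 against 559 CPM (1.58, 1.45 to 1.72). Bst2 is also in the fixed marker list of plasmacytoid dendritic cells, which are counted in this class. Cells so named were 7.79% (19 cells), 5.28% (15) and 8.72% (19) of myeloid-like cells in the control, single and double libraries. A change in the make-up of the class was not separated from a change within its cells. Cxcl10 was at 39.8 against 2.99 CPM, with 24 of 57 UMIs of the double library in 1 cell. In B-like cells the type I interferon list was at −0.07 (percentile 0.15). Its members Usp18 (0.571, 0.430 to 0.754) and Oasl1 (0.625, 0.536 to 0.728), both interferon-induced inhibitors of the response, were lower. The hemoglobin list was at 2.01 in B-like and 1.17 in T-like cells. Erythroid-like cells held 2.22-fold the single share (1.69 to 2.91) and plasma cell-like cells 0.891-fold (0.639 to 1.24).

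**Figure D3:**
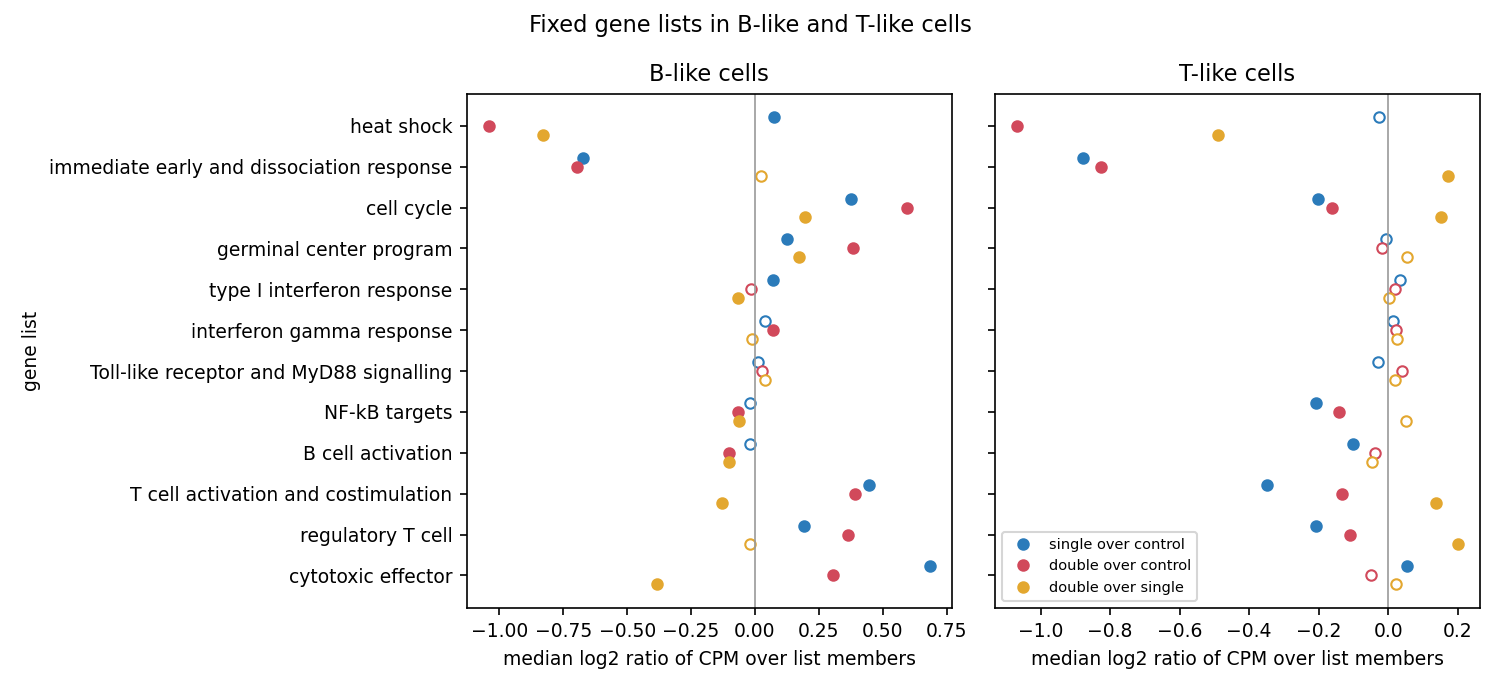
Median log2 ratio of gene lists in B-like and T-like cells for the 3 comparisons. Filled points lie outside the central 95% of 10000 matched random lists and open points inside.

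Antibody class switching asked whether the exposed libraries held more cells with a switched heavy chain. Among B-like cells 1.01% (48 of 4741), 1.40% (66 of 4720) and 1.49% (62 of 4151) were called switched in the control, single and double libraries. With at least 10 UMIs per call the switched percentages of B-like cells were 2.36%, 2.43% and 1.91%. Among plasma cell-like cells the values were 18.0% (20 of 111), 19.4% (18 of 93) and 21.5% (14 of 65). Among germinal center-like cells they were 24.6% (16 of 65, 14.8 to 36.9%), 34.2% (38 of 111, 25.5 to 43.8%) and 34.9% (30 of 86, 24.9 to 45.9%). The order of the germinal center-like values was not stable: with at least 10 UMIs per call the single and double libraries gave 20.8% and 14.7%, both below the control library at that setting.

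The share of germinal center-like cells with Ighg1 differed between the exposed libraries. Ighg1 was the top isotype in 7.69% (5 cells), 19.8% (22 cells, 12.9 to 28.5%) and 3.49% (3 cells, 0.725 to 9.86%), with 16 of the 22 cells of the single library among those with Igkv14-111 as the top kappa gene. Ighg2b was the top isotype in 6.15% (4 cells), 10.8% (12 cells, 5.71 to 18.1%) and 20.9% (18 cells, 12.9 to 31.0%), and held 7.57%, 16.3% and 15.7% of heavy chain UMIs. These constant genes lie on chromosome 12 (Ighg1, 113325240 to 113330523, ENSMUSG00000076614; Ighg2b, 113302965 to 113307933, ENSMUSG00000076613; Ighg2c, 113285325 to 113288932, ENSMUSG00000076612). They are close in sequence, so the assignment of UMIs among them is uncertain. In plasma cell-like cells Ighg1 held 1.45%, 6.76% and 0.0342% of heavy chain UMIs, Ighg2c 4.14%, 2.49% and 9.73%, and Ighg3 0.120%, 4.0% and 6.30%. These shares rest on few cells: the gene was the top isotype in 2, 5 and 0 cells for Ighg1, 2, 2 and 4 for Ighg2c, and 0, 3 and 5 for Ighg3.

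**Figure D4:**
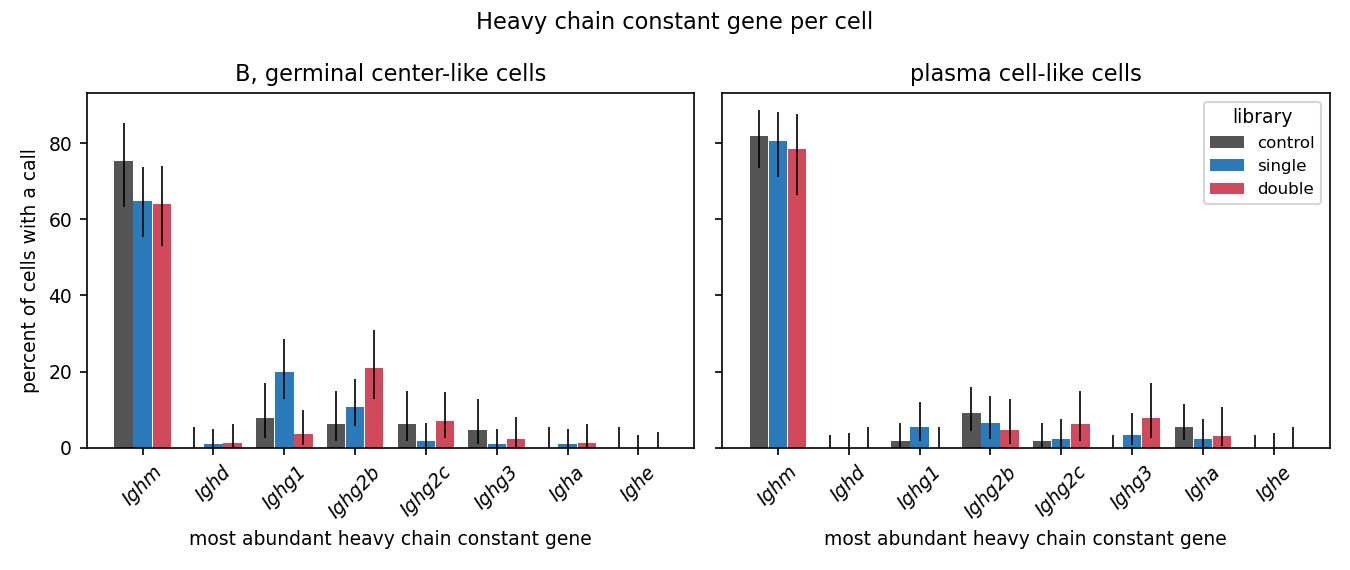
Most abundant heavy chain constant gene per germinal center-like and plasma cell-like cell in the 3 libraries. Intervals are exact binomial 95% intervals over cells.

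A few variable genes, chosen after their values were seen, were common within 1 library, and no receptor sequences were compared. In the single library 24 of 111 germinal center-like cells (21.6%, 14.4 to 30.4%) had Igkv14-111 as the top kappa variable gene, against 3 of 59 (5.08%) in the control and 1 of 84 (1.19%) in the double library. Of those with a heavy chain call, 12 of 20 had Ighv1-39, and 16 of the 24 had Ighg1 as the top isotype. Over all B-like cells Igkv14-111 was at 2.34%, 2.67% and 2.43%. In the double library 15 of 64 plasma cell-like cells (23.4%, 13.8 to 35.7%) had Ighv1-9, of which 13 had Ighm, against 4 of 109 in the control and 2 of 93 in the single library.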

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

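Every test of an explanation named in this part was chosen after the result it concerns had been seen. The values below stood out because a gene list lay on opposite sides in different classes of the same comparison, or because an exposed library lost or left unnamed more cells than control. The difference between classes was not tested in any case.

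Several of these values came from lists of 1 lymphocyte class measured in another class. The T cell activation list was at 0.45 in B-like and −0.35 in T-like cells for single over control, at 0.39 and −0.13 for double over control, and at −0.13 and 0.14 for double over single. The regulatory T list was at 0.19 in B-like and −0.21 in T-like cells for single over control, and at 0.36 and −0.11 for double over control. The B cell receptor list was at 0.29 in T-like and −0.15 in myeloid-like cells for double over single, but the T-like value was −0.16 with predicted doublets kept and −0.03 without T-like cells that had a Cd79a or Cd79b UMI. T cells that fell into B-like clusters, or pairs of cells in 1 droplet, could give the values in the class that should lack the transcripts, but the explanation stays open. In B-like cells without a Cd3e or Cd3d UMI, 6 T transcripts had a single over control log2 ratio of 0.25, against 1.41 in all B-like cells. Weighted by those T transcripts, B-like cells of the control, single and double libraries held 1.12-fold (0.977 to 1.26), 0.625-fold (0.469 to 0.846) and 0.571-fold (0.353 to 0.969) the mean B transcripts. Those T transcripts include Ccl5, of which 1 B-like cell held 371 of 566 UMIs in the double library. Without the germinal center-like cluster the T cell activation list in B-like cells was at −0.04 for single and −0.18 for double over control. That cluster held 4, 21 and 10 cells with T transcripts only in the control, single and double libraries.

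Cell cycle transcripts lay on opposite sides in B-like and T-like cells over control, and for single over control also in B-like and myeloid-like cells. The cell cycle list was at 0.38 in B-like, −0.20 in T-like and −0.60 in myeloid-like cells for single over control, and at 0.60 in B-like and −0.16 in T-like cells for double over control. The germinal center list was at 0.12 in B-like and −0.29 in myeloid-like cells for single over control. Without the germinal center-like cluster the B-like cell cycle medians were −0.11 and −0.13. That cluster was formed and named on such genes, so its removal does not locate the difference. It held 4, 21 and 10 cells with T transcripts only in the control, single and double libraries. For single over control the B-like cell cycle median was 0.09 without B-like cells that had a Cd3e or Cd3d UMI. Cycling T cells counted as B-like were therefore not separated from a difference in proliferation between the classes.

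The immunoglobulin list was at 0.43 in T-like and −0.44 in myeloid-like cells for single over control, at 1.20 and −1.81 for double over control, and at 0.71 and −0.26 for double over single. In control myeloid-like cells 660 of 663 Jchain UMIs (99.5%) lay in 1 cell. The neutrophil granule list was at 2.84 in myeloid-like and −0.67 in B-like cells for double over control, and at 3.81 and −1.13 for double over single. The myeloid-like values rest on Elane and Prtn3, with 80 of 81 and 75 of 86 UMIs of the double library in 1 cell, so they describe individual cells and not the class. The B-like values rest on 3 measured members and were 0.62 and 0.65 with members of at least 100 UMIs, so the B-like side was not stable.

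Losses to the filters and the total of unnamed cells differed slightly, while clusters of cells with few UMIs differed more. The filters removed 0.363% of barcodes in the single and 0.243% in the double library, against 0.232% in control. Unnamed cells were 4.71% of the single library, against 4.44% in control. Among them, clusters 24 and 25 were left unnamed for low UMIs (medians 1026 and 845.5) without an own marker among their top 10 genes. Cluster 24 was 0.460%, 0.637% and 0.130% of the control, single and double libraries, and cluster 25 was 0.259%, 0.450% and 0.0866%.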

How the results depend on the processing

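The 23 alternatives fixed in advance and the 7 chosen after seeing the data were all run, but only a selection of values is given, by setting. It holds each value that changed side, and of those that moved only class shares, key lists and switched percentages, so most moved values of other lists and named genes are not given. The 2 other scalings and the mean over cells moved only such values. Leaving out germinal center-like cells with T transcripts only, chosen after seeing the data, and calling isotypes from at least 1 UMI moved none. Settings chosen after seeing the data are named as such. Values are folds for shares and named genes and median log2 ratios for lists, in the order single over control, double over control, double over single unless said otherwise. No paired analysis was possible because each group is 1 library. A value stayed when it lay inside the counting interval, or for a list within 1 SD of the medians of its random lists. A change of side was counted for shares whose interval excluded 1 and lists outside the central 95% of random lists, and for any named gene. Of 294 alternative values of class shares, 258 stayed, 23 moved and 13 lay on the other side of 1. Of 300 values of the key lists 241 stayed, 55 moved and 4 changed sign. Of 1404 values of the other lists 1170 stayed, 217 moved and 17 changed sign. Of 310 values of named genes 269 stayed, 37 moved and 4 changed side, and of 27 switched percentages 23 stayed and 4 moved. The cause of these changes was not tested.

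With each cell classed from its own markers, the B-like share was 0.970 (single over control) and the germinal center-like share 1.26 and 0.957 (the first 2 comparisons), against 1.80 and 1.62. The transitional-like share was 0.965, 0.914 and 0.948. The marginal zone-like share was 0.925 (double over control) and 0.900 (double over single). The follicular helper-like share was 1.05 and 0.858 in those comparisons, and the regulatory T-like share 1.02 and 1.14 over control.

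Other clustering settings moved mainly the marginal zone-like and transitional-like shares. After thinning to 1000 UMIs the myeloid-like share was 1.24 (single over control), and for double over control the marginal zone-like share was 0.946 and the regulatory T-like share 1.15. At resolution 0.6 the marginal zone-like share was 1.34 and 1.14 over control and the regulatory T-like share 1.15 (double over control). At resolution 2 the marginal zone-like share was 1.40 and 1.18. With immunoglobulin and T cell receptor genes kept for clustering the transitional-like share was 1.69 and 2.31 over control. With stress genes left out of the clustering, chosen after seeing the data, it was 0.770 and 1.22.

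With at most 5% mitochondrial UMIs the transitional-like share was 0.946 (single over control) and 1.69 (double over single), and the marginal zone-like share 1.27, 1.12 and 0.883. In B-like cells the immediate early list was −0.60 (double over control), the heat shock list −0.71 (double over single), the germinal center list 0.20 (single over control) and the cell cycle list 0.66 (double over control). In T-like cells for single over control the immediate early list was −0.96, the T cell activation list −0.30 and the regulatory T list −0.29, and for double over single the heat shock list was −0.54.

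With at least 1000 UMIs per cell the transitional-like share was 1.003 and 1.41 over control and the marginal zone-like share 1.25 and 1.02. With predicted doublets kept the marginal zone-like share was 1.21, 1.03 and 0.856. The heat shock list was then −0.88 in B-like and −0.47 in T-like cells (double over single), the T cell activation list −0.18 in T-like cells (double over control) and the B cell receptor list −0.16 in T-like cells (double over single).

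Without cluster 5, chosen after seeing the data, the B-like lists were as follows. This removed 2181 control, 222 single and 105 double cells, so it also changed the make-up of the control B-like cells most. The type I interferon list was 0.0431 and −0.0474 over control, the Toll-like receptor list −0.0312 (single over control), the immediate early list −0.43, −0.48 and 0.0790, the heat shock list 0.14, −0.84 and −0.79, the germinal center list 0.0660 and 0.25 over control, and the cell cycle list 0.0493 and 0.31 over control.

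Without the germinal center-like cluster, chosen after seeing the data, the B-like germinal center list was 0.0184, 0.0321 and −0.0402 and the cell cycle list −0.11, −0.13 and −0.0105. The cluster was formed and named on such genes, so its removal does not locate the difference. The immediate early list was −0.72, −0.73 and −0.0335, and the heat shock list −1.10 (double over control) and −0.77 (double over single). Over control the cytotoxic list was −0.0686 and −0.28 and the T cell activation list −0.0411 and −0.18. The regulatory T list was −1.23e-05 for single over control.

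Without B-like cells that had a Cd3e or Cd3d UMI and T-like cells that had a Cd79a or Cd79b UMI, chosen after seeing the data, the double over control folds were 0.535 for Ccl5 in B-like cells and 0.891 for H2-Aa, 0.908 for H2-Eb1 and 0.598 for Ly6d in T-like cells. In B-like cells the immediate early list was −0.70 (single over control) and −0.0334 (double over single), the heat shock list −1.07 (double over control) and −0.76 (double over single), the germinal center list 0.49 and the cytotoxic list −0.26 (double over control), the T cell activation list −0.0537 and −0.18 over control, and the cell cycle list 0.0887, 0.41 and 0.32. In T-like cells the type I interferon list was −0.0783 and the heat shock list −0.57 (double over single), the B cell receptor list −0.16 (double over control) and −0.0297 (double over single), the class II list −0.0766, −0.14 and −0.0116, the T cell activation list −0.29 and −0.18 over control, and the regulatory T list −0.16 (single over control). The reversals of B transcripts in T-like cells and of T transcripts in B-like cells came with the removal of cells chosen by transcripts of the same kind.

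With list members down to 10 UMIs, and down to 1 UMI, the B-like immediate early list was −0.0040 (double over single), the germinal center list 0.18 and 0.44 over control, and the T-like regulatory T list −0.26 (single over control). Down to 1 UMI the B-like complement list was 0.10 (double over control). With at least 100 UMIs the B-like neutrophil granule list was 0.62 (double over control) and 0.65 (double over single), and in T-like cells for single over control the type I interferon list was 0.00077, the immediate early list −0.84 and the T cell activation list −0.30.

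With at least 10 UMIs per isotype call, switched cells were 2.36% of control and 2.43% of single B-like cells, and 20.8% of single and 14.7% of double germinal center-like cells.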

Other observations

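All 9 tests of explanations in this part were chosen after related values had been seen. A difference in the germinal center reaction held by clusters and in part otherwise. By clusters, both exposed libraries held more germinal center-like cells than control, with more Mef2b and Gcsam in B-like cells, 1 week after the last dose. The transcripts were higher still after 2 exposures than after 1, at a similar share of cells. Ighg1 was the top isotype in more of these cells in the single than in the double library, but 16 of the 22 Ighg1 cells of the single library had Igkv14-111.

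Interferon and Toll-like receptor lists lay near control in B-like and T-like cells of both exposed libraries at that time. Myeloid-like interferon lists were lower than control in the single library and near control in the double library. In the same cells of the single library the resting T list was at 0.63 and the B cell receptor list at 0.21 over control, and monocyte-like cells were 49.6% of the class against 38.9%, so a change in the make-up of the class was not separated from a change within its cells. No earlier time point was analysed here. The larger germinal center-like share held under some settings and not others: the single over control fold was 1.59 (1.17 to 2.17) after thinning to 1000 UMIs and 1.26 with each cell classed from its own markers, where the double over control fold was 0.957.

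For the germinal center-like share, 3 explanations were tested. A difference in depth was excluded by the thinned fold of 1.59, whose lower bound stayed above 1. Cycling T cells in the cluster were excluded as the sole cause for double over control, since the fold was 1.55 (1.12 to 2.16) without cells that had T transcripts only. These were 4, 21 and 10 cells of the control, single and double libraries. Cells called Igkv14-111 were excluded as the sole cause for single over control, since the fold without them was 1.56 (1.15 to 2.14). A kappa call was made in 59 of 71 control and 111 of 144 single germinal center-like cells. Members of such a clone without a call were kept, so the clone as a whole was not removed. A larger reaction in exposed mice remains a possible explanation, and with 1 library per group a difference between pools of mice could give the same value.

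Heat shock and immediate early transcripts differed across cell classes. A difference in depth was excluded: at 1000 UMIs per cell 9.28% of control T-like cells had an Hspa1a UMI, above the upper bound of the single library (0.875%). A stressed cluster of B-like cells was excluded as the sole cause, since without cluster 5 the single over control fold of Hspa1a plus Hspa1b was 0.137 (0.130 to 0.145). Temperature or handling of a whole library before capture could give the same direction in unrelated cells, and Hsph1 was lower and Rbm3 higher in the double than in the single library in 7 of 7 classes. Against control, the single library had Rbm3 lower in 7 of 7 and Hsph1 higher in 6 of 7, so these genes again lay on opposite sides. Hspa1a was lower than control there, however, so Hspa1a and Hsph1 did not move together. Handling and exposure cannot be told apart here, because each group is 1 library. Activation lists that share genes with the immediate early list, such as those with Cd69 and Nr4a1, may carry the same difference.

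Transcripts of the other lymphocyte class were higher in the exposed libraries. In T-like cells 7 B transcripts (Igkc, Ighm, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ly6d) had log2 ratios of 0.28 (0.24 to 0.32) for single and 0.53 (0.49 to 0.57) for double over control. Leaving out cells with UMIs of at least 2 of 6 other B genes (32, 72 and 63 cells) gave −0.0607 (−0.114 to −0.00749) for double over control, but such cells were chosen by B transcripts, so the drop does not locate the source. Before doublets were removed, barcodes with UMIs of at least 2 of 6 B and 2 of 6 T genes were 3.54%, 5.64% and 3.47% of the control, single and double libraries. The fold was 1.59 (1.41 to 1.81) for single and 0.980 (0.843 to 1.14) for double over control. Of these barcodes 25.3%, 27.7% and 35.1% were left after doublets had been removed. Pairs of a B and a T cell in 1 droplet stay a possible explanation, which for the double library would need more of them to have escaped removal. The part left was larger there, at 35.1% (29.9 to 40.5%) against 25.3% (21.0 to 29.9%) in control. Doublet calls of 2.87%, 4.77% and 2.39% in the control, single and double libraries also lay below the expected 8.60%, 9.89% and 7.57%. Free RNA of B cells spread over all droplets was excluded as the main source: over all T-like cells, with none left out, the median of the 7 B transcripts per UMI had a double over control log2 ratio of −0.10 (−0.19 to 0.01), against 0.53 for the sums. The tests for pairs, free RNA and misplaced T cells replaced earlier ones after those values had been seen, the test for pairs 2 times, and 1 earlier form left free RNA undecided. In B-like cells 6 T transcripts were at 1.41 for single and 1.05 (0.94 to 1.16) for double over control, and at 0.25 (0.11 to 0.38) and −0.22 (−0.37 to −0.07) without cells that had a Cd3e or Cd3d UMI. T cells placed in B-like clusters could give such values. Cells with a Cd3e or Cd3d UMI, counted without thinning, were 2.12%, 2.42% and 1.40% of B-like cells in the control, single and double libraries. Their number did not follow the transcripts, but it can include cells that also held B transcripts, so it does not count misplaced T cells. In the germinal center-like cluster, cells with T transcripts and no Cd79a UMI were 4, 21 and 10. Weighted by T transcripts, B-like cells of the single library held 0.625-fold (0.469 to 0.846) the mean B transcripts, those of the double library 0.571-fold (0.353 to 0.969) and those of control 1.12-fold (0.977 to 1.26). The lower values of the exposed libraries lie in the direction that misplaced T cells would give, but their intervals reach values that pairs of cells could also give, so the explanation stays open. Ccl5 is 1 of the 6 T transcripts, and 1 B-like cell held 371 of its 566 UMIs in the double library. In the single library 1 B-like cell held 103 of 850. The values of the double library therefore depend in part on 1 cell.

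Several values rest on few cells. Gzma in T-like cells came from 36, 31 and 21 cells, and Tnf in myeloid-like cells, at 75.4 CPM in the double library, had 78 of 108 UMIs in 1 cell. The B1-like or age-associated B-like share was 3.02%, 2.29% and 2.86%. Igkv5-39, chosen after its values were seen, was the top kappa gene in 24 of 108, 22 of 93 and 8 of 65 plasma cell-like cells.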
